A study of Homo sapiens with 12 samples.

How the data were processed

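Gene expression was measured in 12 libraries of HaCaT cells, a line of spontaneously immortalized human skin keratinocytes. Per the labels' protocols, cells in buffered saline received 50 J per cm2 of 408 nm light from an LED source at 4.6 mW per cm2. Sessions were held 3 times weekly over a span of at most 14 weeks, and the dose was chosen by the submitters for its toxicity to these cells. Libraries were made from total RNA with QuantSeq 3' mRNA-Seq FWD chemistry, which yields about 1 tag near the 3' end of each transcript. Counts therefore do not need scaling by transcript length, and the use of molecular identifiers is not given in the sources used here.

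The deposited table holds whole-number read counts per gene, not normalized, with 1 column per library. The submitters' processing notes name STAR, featureCounts and the GRCh38 build, without versions or settings. The annotation release, the strand setting and any trimming are not given in the sources used here. Because the strand setting is not stated, counts of antisense genes and of genes that overlap another gene are uncertain, as are counts of near-identical copies. Of 45372 rows, 22754 had a count in any library.

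Groups came from the sample titles: dark or blue light, matched to 3, 14 or 42 irradiations, with 2 libraries per group lettered a and b. Nothing in the labels says that the letters mark separate cultures, so p-values measure the spread between these libraries, which may be technical. In each group the 2 libraries differed by more than sampling noise, with a chi-square per degree of freedom of 1.64 for dark_3 and 5.05 to 8.57 for the other groups, so each library counted as 1 replicate.

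Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at a minimum count of 10, which left 12878, and libraries were scaled by TMM. One quasi-likelihood model with robust estimation held a mean for each of the 6 groups, which left 6 residual degrees of freedom. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all tested genes within a comparison. A gene was called at an adjusted p under 0.05. The comparisons were blue against dark at each irradiation number, the 3 differences between those effects, their average, and the dark controls against each other. Errors beside log2 differences are standard errors derived from the test statistic, and those beside CPM, counts scaled to a common library total, are SD over 2 libraries. The common biological coefficient of variation was 9.41%.

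Before the data were examined, 41 gene lists were fixed, and 36 had at least 5 tested genes. Lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 36 lists. Camera with an estimated correlation and fry were run beside it. Named genes were also chosen by a rule fixed at that time. For blue against dark these were the 12 largest changes each way among called genes with at least 10 CPM in the higher group and both irradiated libraries beyond both dark libraries. The rule took 10 each way for the average and 6 each way for the other comparisons, and 13 stress, differentiation and light-sensing genes whatever their values. Of the genes that met this rule or stood on a list, 5 are not reported here, while all counts of genes include them. Gene positions and types came from GENCODE release 29 on GRCh38, which matched all 12878 tested rows by identifier.

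The scripts were tested on simulated counts in which 200 genes above 10 CPM were changed. Each gene was given the same spread in all libraries, which the real libraries need not share. At 42 irradiations the test recovered 64.7% of genes changed 1.5-fold, 98.5% of those changed 2-fold and all changed 4-fold, with 17 false calls among 12636 genes. At 3 irradiations recovery was 50.0% for 1.5-fold and 93.9% for 2-fold changes, with 6 false calls. At 14 irradiations it was 38.2% and 87.9%, also with 6 false calls.

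Library totals ran from 2073160 to 8183941 counts, and 3 counts correspond to 1.45 CPM in the smallest library and 0.367 CPM in the largest. Ratios of counts for low genes carry exact 95% intervals that cover counting error only. Alternatives set at the start were RLE scaling, DESeq2 1.42.0, no filter and a filter at 5 CPM, the replicate letter as a block, non-robust estimation, fits on the compared libraries alone, and leaving out each library. After the data were seen, further fits added the summed neuronal transcripts as a covariate, left out the 14-irradiation libraries, or thinned counts to lower depth. Further lists were made at that stage. The 10 neuronal genes first noticed and the 4 haemoglobin genes were listed after their levels were seen. Lists of 20 other neuronal, 17 glial and 10 other-organ genes were written down before their sums were looked at.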

Results

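Transcript levels of HaCaT keratinocytes were compared between cells irradiated with blue light and cells kept in the dark, after 3, 14 and 42 irradiations. Each of the 6 combinations had 2 libraries, lettered a and b. Each irradiation number had its own dark controls, so the blue against dark comparisons shared no library. Total counts ranged from 2073160 in blue_14 b to 8183941 in blue_42 b. The other 14-irradiation libraries held 3561392 counts in dark_14 a, 3517401 in blue_14 a and 7950222 in dark_14 b. The remaining libraries held between 6220751 and 7823533 counts. The most abundant gene in each library was MT-RNR2, the large mitochondrial ribosomal RNA, at 4.96% to 6.87% of counts. For genes above 10 CPM the median standard error of a blue against dark log2 difference was 0.142, 0.161 and 0.139 after 3, 14 and 42 irradiations.

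The first comparison asked what changed after 3 irradiations, an early stage of exposure. Only 2 of 12878 genes were called, both higher in irradiated cells and both best known from neurons. SYT1, a calcium sensor of synaptic vesicles, went from 2.11 ± 0.07 to 9.21 ± 3.47 CPM (SD, n = 2), a log2 difference of 2.09 ± 0.33 (SE, edgeR adjusted p = 0.0388). CELF4, an RNA-binding protein, went from 0.22 ± 0.09 to 2.88 ± 0.51 CPM, with an edgeR adjusted p of 0.0483. It rested on 3 counts in dark_3 against 39 in blue_3, a ratio of 12.6 with a 95% counting interval of 4.02 to 63.9. Both lay below 10 CPM and were named after their values were seen, because the count was so small. Over the fits that left out 1 library the count ran from 0 to 6, with no call without dark_3 a, dark_3 b, blue_3 b or any irradiated library at 14 or 42, 4 without dark_14 a and 6 without dark_42 a or dark_42 b. In the same libraries 10 neuronal transcripts, picked after their levels were seen and including SYT1 and CELF4, summed to 7.68 CPM in dark_3 and 37.3 CPM in blue_3. Another 20, listed before they were looked at, summed to 42.3 and 59.1 CPM, a log2 difference of 0.47 ± 0.15 (adjusted p = 0.475 over all genes).

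Gene lists after 3 irradiations passed only by camera at the preset correlation, where 7 of the 36 ranked higher and 3 lower in irradiated cells. With an estimated correlation none of these 10 passed, at adjusted p = 0.208 to 0.768, and fry called none. Cholesterol biosynthesis had 20 of 23 members above 0, with a median log2 difference of 0.15 (adjusted p = 0.00213), and fatty acid synthesis had 16 of 20 (adjusted p = 0.00915). On the latter list SCD, the stearoyl-CoA desaturase, differed by 0.43 ± 0.11 and FASN, the fatty acid synthase, by 0.43 ± 0.12, and these 2 passed when adjusted over the list alone. Interferon-stimulated genes had 24 of 33 members above 0 (adjusted p = 0.00213), among them MX1, an antiviral GTPase, at 0.60 ± 0.19. Stress keratins and alarmins had a median of 0.49 (adjusted p = 0.00213), with KRT17 at 0.48 ± 0.12. Mesenchymal genes had 18 of 23 above 0 (adjusted p = 0.00213), with the collagen gene COL5A1 at 1.03 ± 0.35. Fibroblast markers summed to 4.18 and 4.98 CPM in the dark_3 libraries and 8.11 and 9 CPM in blue_3, of which THY1, also among the 10 neuronal transcripts, had means of 0.37 and 2.47 CPM. Leukocyte markers summed to 2.94 and 2.56 CPM in dark_3 and 6.54 and 5.47 CPM in blue_3. MHC class I presentation (adjusted p = 0.00944) and senescence-associated genes (adjusted p = 0.0472) also ranked higher. Lists that ranked lower were G1/S genes, with 4 of 30 members above 0 (adjusted p = 0.0058), EGFR ligands and feedback genes, with 4 of 19 (adjusted p = 0.0058), and heat shock genes, with 3 of 18 (adjusted p = 0.0233). The heat shock list had a median of -0.18 but a mean of 0.03, owing to CRYAB at 3.12 ± 1.01. No member of any list was called over all genes. Without blue_3 a no list passed at the preset correlation either.

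After 14 irradiations no gene was called by edgeR, 758 of 12878 had an unadjusted p under 0.05, and DESeq2 called 2. The smallest adjusted p was 0.552. Without blue_14 a 11 genes were called, and 1 without each of the other 14-irradiation libraries. The group included the smallest library. In simulated counts of the same size 87.9% of 2-fold changes were recovered, with 200 genes above 10 CPM changed. The simulation gave each gene the same spread in all libraries. The real blue_14 libraries differed most, with an SD of log2 differences of 0.349, against 0.159 to 0.271 in the other groups. Recovery in these libraries may therefore be lower than simulated. Of the gene lists, 9 ranked higher and 1 lower by camera at the preset correlation, while none passed with an estimated correlation, at adjusted p = 0.137 to 0.658 for these 10, or by fry. Immediate early genes, many of them transcription factors, are switched on within minutes of stimulation. This list had the smallest adjusted p, with 15 of 19 members above 0 and a median of 0.24 (camera adjusted p = 7.31e-07). None was called over all genes, and 3 were higher when adjusted over the list alone. These were EGR1 at 1.16 ± 0.24, EGR3 at 2.44 ± 0.73 and MYC at 0.61 ± 0.20. Basal keratinocyte adhesion had 16 of 18 members above 0 (adjusted p = 0.00576), with TP63, the master regulator of basal keratinocytes, at 0.55 ± 0.15. Targets of the aryl hydrocarbon receptor had 6 of 7 above 0 (adjusted p = 0.00576), with CYP1B1 at 0.27 ± 0.12. Hypoxia and glycolysis genes (adjusted p = 0.00919), MHC class I presentation (adjusted p = 0.0151), alarmins (adjusted p = 0.0194), senescence-associated genes (adjusted p = 0.0206), NRF2 targets (adjusted p = 0.0295) and autophagy genes (adjusted p = 0.0315) ranked higher as well. Cytosolic ribosomal protein genes ranked lower, with 9 of 36 above 0 and a median of -0.06 (adjusted p = 0.0253). Without blue_14 b or without dark_14 b 4 lists passed at the preset correlation, and without dark_14 a 17 did. The 10 neuronal transcripts summed to 76.8 CPM in dark_14 and 27.2 CPM in blue_14, and the other 20 to 88.6 and 48.1 CPM.

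After 42 irradiations 158 genes were called, 108 higher and 50 lower in irradiated cells, and all 158 had both irradiated libraries beyond both dark libraries. Such separation held for 42.2% of all tested genes, where chance gives 33.3%. The largest rise was in SFRP1, a secreted inhibitor of Wnt signalling. It stood at 3.55 ± 0.13 CPM in dark_42 and 50.5 ± 7.45 CPM in blue_42 (SD, n = 2), 14.2-fold higher, with a log2 difference of 3.82 ± 0.19 (adjusted p = 7.41e-11). SFRP1 (ENSG00000104332) lies on the minus strand of chromosome 8 from 41261958 to 41309497 on GRCh38. OLFM4 (ENSG00000102837, chromosome 13 from 53028759 to 53052057), a secreted olfactomedin glycoprotein, rose from 12.4 ± 1.69 to 38.1 ± 1.70 CPM, a log2 difference of 1.62 ± 0.16 (adjusted p = 7.8e-06). The largest negative difference was in B3GALT5 (ENSG00000183778, chromosome 21 from 39556442 to 39673137), a galactosyltransferase of glycan synthesis. It stood at 13.2 ± 0.33 CPM in dark_42 and 1.75 ± 0.08 CPM in blue_42, 7.44-fold lower, with a log2 difference of -2.90 ± 0.28 (adjusted p = 7.8e-06). Its level rose in the dark series, from 2.34 CPM in dark_3 and 9.5 in dark_14, while blue_3 held 2.35 CPM and blue_14 2.68.

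Among the other higher genes, CALD1, the actin-binding caldesmon, rose 2.21-fold (log2 1.14 ± 0.13, adjusted p = 4e-05). PTK7, a pseudokinase of planar cell polarity, rose 2.16-fold (log2 1.11 ± 0.15, adjusted p = 0.000625). GJA1, which encodes the gap junction protein connexin 43, rose 2.17-fold (log2 1.12 ± 0.25, adjusted p = 0.0252), and the adhesion gene IGSF9 rose 2.43-fold (log2 1.28 ± 0.20, adjusted p = 0.00204). The microtubule-associated EML2 rose by 1.02 ± 0.22 and the anoctamin ANO8 by 1.39 ± 0.23. The elastase inhibitor PI3 went from 23.3 ± 4.36 to 92.3 ± 25.7 CPM (adjusted p = 0.0476). DHRS1, a dehydrogenase, rose by 1.16 ± 0.17, LRRC41 by 1.07 ± 0.19 and MED24, a subunit of the Mediator complex, by 0.99 ± 0.13. These rises are relative to dark_42, which for all of these genes but PI3 lay below both dark_3 and dark_14. MED24 stood at 129 CPM in dark_3, 113 in dark_14, 45.8 in dark_42 and 90.7 in blue_42. PTK7 stood at 91.9, 107, 45.5 and 98.4 CPM in the same order. Only CALD1, GJA1, PI3 and LRRC41 had a higher mean in blue_42 than in both earlier dark groups. Without 1 library GJA1 ranged from 0.67, without blue_42 a, to 1.47, and lost its call there and without dark_42 b, while EML2 and PI3 each kept theirs in 4 of 12 such fits. Gene types in the annotation were protein-coding for all of these.

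Among the lower genes, BMP3 had a log2 difference of -1.36 ± 0.22, the TGF-beta co-receptor TGFBR3 of -1.10 ± 0.22 and the growth factor FGF2 of -1.04 ± 0.19. FGF2 stood at 23.1 ± 4.63 CPM in dark_42 and 11.2 ± 0.22 CPM in blue_42. The ubiquitin-like ISG15 differed by -1.01 ± 0.18 and the transcription factor KLF4 by -0.97 ± 0.15. PPM1L, a phosphatase, the centrosomal CEP192 and the scaffold SASH1 each differed by -0.97, EPB41L4A by -0.96 ± 0.16 and the adhesion molecule CEACAM6 by -0.96 ± 0.19. Adjusted p-values of these 10 genes lay between 0.00275 and 0.0264.

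**Figure D1:**
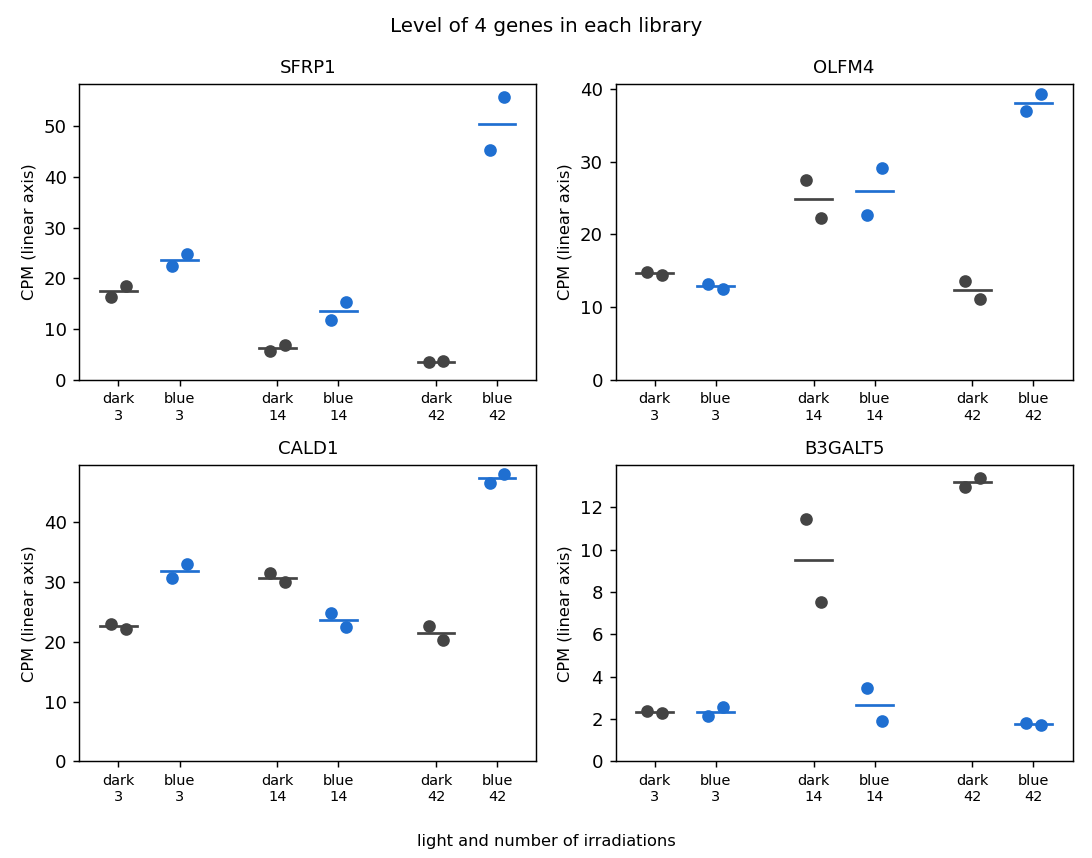
Level in CPM (linear axes) of SFRP1, OLFM4, CALD1 and B3GALT5 in each library, by light and number of irradiations. Points are the 2 libraries of a group and lines their mean; SFRP1 averages 3.55 CPM in dark_42 and 50.5 CPM in blue_42.

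By list, interferon-stimulated genes were lower in blue_42 than in dark_42. Relative to the dark_3 mean, their mean log2 level was 1.32 and 0.99 in the dark_42 libraries and 0.96 and 0.76 in blue_42. In dark_14 it was 0.86 and 0.85, so blue_42 lay near dark_14 and above dark_3. Of 33 tested members, 9 were called lower and none higher, and 12 were lower when adjusted over the list alone. The median log2 difference was -0.28 (camera adjusted p = 1.28e-12), against adjusted p = 0.231 with an estimated correlation and 0.0423 by fry. The called members were ISG15, OASL at -0.82 ± 0.11, IFIT2 at -0.80 ± 0.12, HERC5 at -0.94 ± 0.16, IFI44 at -0.91 ± 0.16, DDX60 at -0.79 ± 0.13, IFIT3 at -0.53 ± 0.13, and the RNA sensors RIGI at -0.80 ± 0.13 and IFIH1 at -0.57 ± 0.13. Mitochondrially encoded transcripts were higher in blue_42 than in dark_42, with 14 of 15 above 0 and a median of 0.51 (camera adjusted p = 7.94e-12). This stood against adjusted p = 0.231 with an estimated correlation and 0.0423 by fry. Relative to the dark_3 mean, their mean log2 level was -0.334 and -0.484 in dark_42 and 0.108 and 0 in blue_42. The called members were MT-ND4 at 0.63 ± 0.14, MT-ND5 at 0.52 ± 0.12 and MT-CO1 at 0.51 ± 0.12, and 10 passed over the list alone. Mitochondrial genes held 12.6% and 12.4% of counts in the dark_42 libraries, 15.4% and 13.8% in blue_42, and 13.7% to 16.1% in the remaining libraries. Both list calls held in all 12 fits that left out 1 library.

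Further lists passed with higher adjusted p. Stress keratins and alarmins had 12 of 13 members above 0 and a median of 0.57 (adjusted p = 0.014), with PI3 called. Matrix metalloproteinases and related genes had 2 members called higher (adjusted p = 0.022), the sheddase ADAM19 at 0.73 ± 0.15 and PLAUR, the urokinase receptor, at 0.75 ± 0.17, so neither is itself a matrix metalloproteinase. Hypoxia and glycolysis genes ranked higher (adjusted p = 0.0319), as did ATF4 and CHOP targets (adjusted p = 0.0457), with no member called in either. When adjusted over the list alone, 3 hypoxia genes were higher, while of the ATF4 and CHOP targets 3 were higher and 1 lower. Double-strand break repair genes ranked lower, with 4 of 25 above 0 and no call (adjusted p = 0.0165). These 5 lists had adjusted p = 0.241 to 0.692 with an estimated correlation, and all but ATF4 and CHOP targets lost the call without dark_42 a or without blue_42 b. ATF4 and CHOP targets lost it without dark_14 a, dark_14 b, dark_42 b or blue_42 a instead. Their median log2 difference ran from 0.115 to 0.467 over the fits that left out 1 library. Single members called on other lists included CLDN1 at 0.58 ± 0.11, FASN at 0.54 ± 0.12, CDH2 at 0.52 ± 0.11 and MT1X at 0.55 ± 0.14.

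**Figure D2:**
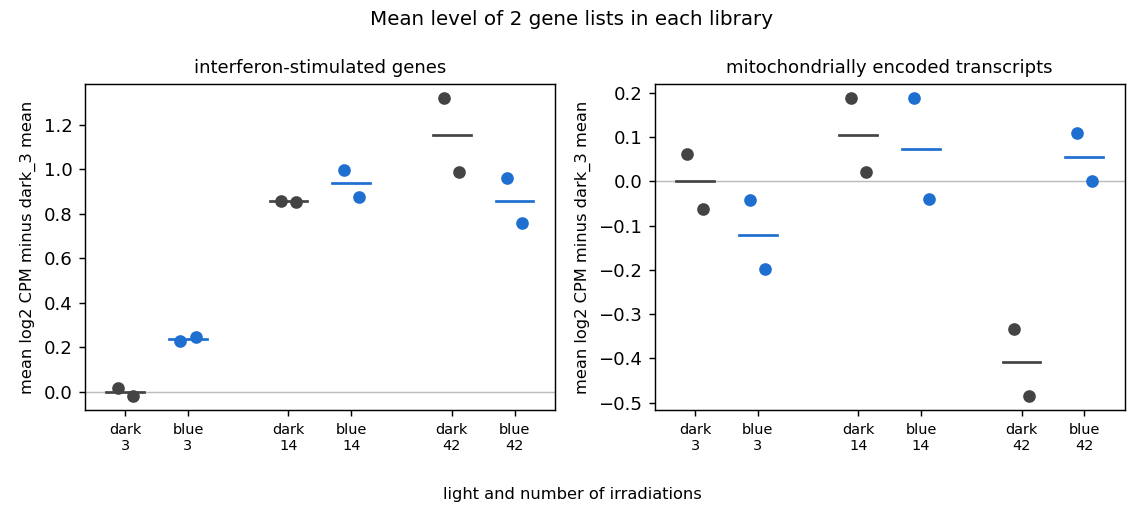
Mean log2 CPM of the interferon-stimulated genes (left) and the mitochondrially encoded transcripts (right) in each library, as the difference from the dark_3 mean. Points are libraries and lines group means; interferon-stimulated genes lie at 1.32 and 0.99 in dark_42 and at 0.96 and 0.76 in blue_42.

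The number of calls after 42 irradiations depended on single libraries. It was 24 without blue_42 b, 32 without blue_42 a, 35 without dark_42 b, 99 without either dark_3 library and 246 without the 14-irradiation libraries, where an arm left with 1 library is assumed to vary like the others. Of the 24 genes named by rule, 7 were called in all 12 leave-one-out fits, namely SFRP1, OLFM4, CALD1, PTK7, MED24, IGSF9 and B3GALT5.

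Genes chosen for their known links to light stress, cell cycle and differentiation gave no call in any of the blue against dark comparisons of the main model. HMOX1, the haem oxygenase induced by oxidants, differed by 1.35 ± 0.49 after 3 irradiations (adjusted p = 0.56), 0.15 ± 0.49 after 14 and -0.05 ± 0.42 after 42. The value after 3 was 0.69 without blue_3 b and 1.86 without blue_3 a. CDKN1A, the p53-induced cell cycle inhibitor, differed by 0.53 ± 0.16 (adjusted p = 0.443), -0.04 ± 0.17 and -0.06 ± 0.16 in the same order. The cornified envelope gene IVL differed by 0.75 ± 0.15 after 3 irradiations (adjusted p = 0.138), and was called without dark_14 a, dark_14 b, dark_42 a or dark_42 b, without a filter on low counts and with only the libraries compared. The collagenase MMP1 differed by 1.63 ± 0.54 after 14 irradiations (adjusted p = 0.767), at 1.06 without dark_14 b and 2.18 without blue_14 a. It stood at only 1.51 ± 0.69 CPM in dark_14 and 4.54 ± 2.36 in blue_14, where 3 counts correspond to 0.377 to 1.45 CPM. Group means were as low for HMOX1, at 1.06 to 3.35 CPM, and GDF15, at 0.99 to 4.21 CPM, so these values rest on few counts. The proliferation marker MKI67 differed by -0.16 ± 0.14, the basal keratin KRT5 by 0.60 ± 0.25 and the opsin OPN3 by 0.34 ± 0.13 after 42 irradiations, with adjusted p = 0.667, 0.346 and 0.228. Without 1 library MKI67 ranged from -0.27 to -0.05, and KRT5 from 0.32 without blue_42 a to 0.83 without blue_42 b. GDF15, KRT1, KRT10, KRT14, CXCL8 and IL1B were likewise not called.

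The title of the series speaks of stage-specific changes, so the difference between the blue light effects was itself tested. Between 42 and 3 irradiations 56 genes differed, 35 with a more positive and 21 with a more negative effect at 42. SFRP1 differed by 3.39 ± 0.26 (adjusted p = 2.52e-07), and OLFM4, the calcium-binding CALB2, LRRC41, FLG and SAMD10 also had the more positive effect at 42. FLG, which encodes the epidermal barrier protein filaggrin, went from 61.6 to 34.5 CPM at 3 irradiations and from 43.0 to 62.9 CPM at 42. B3GALT5, BMP3, CEACAM6, the scaffold NEDD9 and ISG15 had the more negative effect at 42. Between 42 and 14 irradiations 7 genes differed, among them SFRP1, OLFM4, CALD1, MED24 and CDH2 with the more positive and VAV3 with the more negative effect at 42. Between 14 and 3 irradiations 5 genes differed, all with a more negative effect at 14, namely SYT1, CELF4, NEFM, MAP2 and MRFAP1L1. SYT1, CELF4, NEFM and MAP2 are characteristic of neurons, and CELF4 and NEFM were named because the count was small. Interferon-stimulated genes ranked lower and mitochondrially encoded transcripts higher in the effect at 42 than at 3 (camera adjusted p = 4.1e-14 and 3.67e-11) and than at 14 (7.01e-10 and 2.36e-09). With an estimated correlation these had adjusted p = 0.265 against 3 and 0.394 against 14. Of the named differences between 42 and 3, those of SFRP1 and OLFM4 were called in all 12 fits that left out 1 library and the others in 6 to 9. Between 42 and 14 these numbers were 12 for SFRP1 and CALD1, 10 for OLFM4, 4 for MED24 and 2 for CDH2 and VAV3, and between 14 and 3 they were 12 for SYT1, 6 for CELF4 and MRFAP1L1, 4 for NEFM and 3 for MAP2. The 56 calls fell to 2 without blue_42 b or dark_3 b, 3 without blue_3 b, 4 without dark_3 a or blue_42 a and 27 without dark_42 b, and rose to 171 without blue_3 a and 209 without dark_42 a. The 5 calls between 14 and 3 became 36 to 38 without blue_3 a, dark_42 a or dark_42 b and 1 or 2 without either dark_3 library, blue_3 b or either blue_42 library, while the 7 between 42 and 14 became 53 without blue_14 a, 49 without dark_42 a and 2 without dark_42 b or blue_42 b.

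No gene was called in the same direction at 2 irradiation numbers, while independent lists of these lengths would share 0.017 genes between 3 and 42. Across genes, which are not independent replicates, Pearson's r between the log2 differences was -0.20 for 3 and 14, -0.02 for 3 and 42, and 0.10 for 14 and 42 irradiations. Of the 158 genes called at 42, 71 had the same sign at 3 and 110 at 14. Averaged over the 3 irradiation numbers, 9 genes were called, 8 higher and 1 lower. By the naming rule these included SFRP1 at 1.76 ± 0.12 (adjusted p = 3.73e-08), C1orf21 at 0.59 ± 0.10, DHRS1 at 0.57 ± 0.10, the tight junction gene CLDN1 at 0.37 ± 0.07, the tropomyosin gene TPM1 at 0.34 ± 0.06 and, lower, B3GALT5 at -1.52 ± 0.20 (adjusted p = 0.00153). Of these, SFRP1 and B3GALT5 were called in all 12 fits that left out 1 library, C1orf21 in 5, DHRS1 and CLDN1 in 4 and TPM1 in 2. The level of CLDN1 was 165 CPM in dark_3 and 188 in blue_3, 257 and 327 at 14, and 215 and 321 at 42. That of B3GALT5 was 2.34 CPM in dark_3 and 2.35 in blue_3, 9.5 and 2.68 at 14, and 13.2 and 1.75 at 42, so its average did not come from 3 irradiations. Leaving out single libraries gave between 2 and 22 calls, the lowest without either dark_3 library, blue_3 a, dark_42 a or blue_42 b and the highest without dark_14 a.

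The dark controls differed from each other far more than irradiated cells did from their controls. From dark_3 to dark_42 1220 genes rose and 1064 fell, from dark_3 to dark_14 1044 rose and 594 fell, and from dark_14 to dark_42 233 rose and 674 fell. Interferon-stimulated genes rose, with 22 of 33 called higher in dark_14 and 28 of 33 in dark_42 relative to dark_3. The median at 42 was 1.15 (camera adjusted p = 2.88e-39), and adjusted p = 0.0281 with an estimated correlation. At 14 the median was 0.82 (adjusted p = 2.1e-25), and adjusted p = 0.0766 with an estimated correlation. OASL rose by 1.92 ± 0.12, RSAD2 by 1.72 ± 0.15 and DDX60 by 1.75 ± 0.14 from dark_3 to dark_42. Inflammatory genes had 11 of 18 called higher and 1 lower at 42 (adjusted p = 6.79e-08, and 0.36 with an estimated correlation), including IL1A at 1.72 ± 0.27 and BIRC3 at 2.29 ± 0.27. MHC class I presentation had 8 of 12 called higher at 42 (adjusted p = 3.54e-05, and 0.385 with an estimated correlation), with ERAP1 at 1.18 ± 0.17. Leukocyte markers, which include CD74, summed to 2.94 and 2.56 CPM in the dark_3 libraries and 19.8 and 54.7 CPM in dark_42. Among the largest rises, LCN2, a siderophore-binding lipocalin, went from 45.2 ± 2.06 CPM in dark_3 to 712 ± 330 in dark_42, and SAA2, an acute-phase protein, from 4.16 ± 0.39 to 84.7 ± 33.3. PI3, FRMD3, CD74 and SERPINB4 also rose, CD74 and SERPINB4 with a call in 3 of 12 fits that left out 1 library and PI3 in 10, and counts of SAA2 and SERPINB4 are uncertain because near-identical copies share reads.

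Other genes fell in the dark over the same interval. Heat shock genes had 10 of 18 called lower at 42 (adjusted p = 1.15e-06, and 0.36 with an estimated correlation), with HSP90AB1 at -0.65 ± 0.13, and G1/S genes had 7 of 30 (adjusted p = 7.57e-05, and 0.55), with MCM5 at -0.71 ± 0.12. Mitochondrially encoded transcripts had 4 of 15 called lower at 42 relative to 3 (adjusted p = 0.00117, and 0.433 with an estimated correlation) and 7 of 15 relative to 14 (adjusted p = 3.46e-08, and 0.32). Keratinocyte terminal differentiation genes had 5 of 17 called lower and 2 higher at 42 relative to 3 (adjusted p = 0.00807, and 0.36 with an estimated correlation). By size the leading falls were CACNG4 at -2.39 ± 0.24, BMP4 at -2.34 ± 0.25, SFRP1 at -2.29 ± 0.21, KRT81 at -2.13 ± 0.56, SLC7A8 at -2.04 ± 0.26 and SPON2 at -2.04 ± 0.19. KRT81 kept its call in 4 of 12 fits that left out 1 library and the others in all 12. SFRP1 thus moved down in the dark series, from 17.5 ± 1.59 CPM at 3 to 6.31 ± 0.83 at 14 and 3.55 ± 0.13 at 42. From dark_3 to dark_14 STMN3, ODC1, THBS1 and VPS9D1-AS1 fell too, the last an antisense RNA of uncertain count, while ODC1 ranged from -2.02 to -0.99 over those fits and was called in 11. Without 1 dark_3 library the 2284 calls from dark_3 to dark_42 became 765 or 840, and without dark_42 b 833. The 1638 calls from dark_3 to dark_14 became 336 or 406 without 1 dark_3 library and 421 without dark_14 a.

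Neuronal transcripts were higher in the dark_14 libraries. The 20 neuronal genes listed before they were looked at rose from dark_3 to dark_14 by 1.07 ± 0.15 in sum, and 17 glial genes listed likewise differed by -0.33 ± 0.23. Of these, UGT8 and PTPRZ1 held 92.3 of 97.6 CPM in dark_3, and the other 15, set apart after the sum was seen, rose by 1.42 ± 0.30 (adjusted p = 0.00469 over all genes). HBB, a haemoglobin chain of red blood cells, rose by 4.72 ± 1.10 (adjusted p = 0.0357) to 16.5 ± 17.3 CPM in dark_14. Its call held in 4 of 12 fits that left out 1 library, and its log2 difference ran from 2.62 without dark_14 b to 5.34 without dark_14 a. From dark_14 to dark_42 FAM107A, SPARCL1, SNAP25, MAP1B and SYT1 were among the leading falls, at -3.79 ± 0.47, -3.74 ± 0.65, -3.09 ± 0.65, -2.93 ± 0.50 and -2.64 ± 0.28. In such fits FAM107A and SYT1 kept these calls in all 12, MAP1B in 10, and SPARCL1 and SNAP25 in 9 each. The log2 differences ran from -4.55 without dark_42 a to -2.20 without dark_42 b for MAP1B, from -4.79 to -3.14 for SPARCL1 and from -4.31 to -2.44 for SNAP25, without the same libraries. The leading rises over that interval were GNG11, ZNF618, PDIA5, TXNDC16, GKAP1 and RNF4, at 0.98 to 1.67. Of these, GNG11 and ZNF618 were called in all 12 such fits, with GNG11 at up to 2.72 without dark_14 b, and the others in 8 to 11, with TXNDC16 as low as 0.66. With the summed neuronal transcripts as a covariate, chosen after the data were seen, 28 genes were called between dark_14 and dark_3, none between dark_42 and dark_14, and 2045 between dark_42 and dark_3. The 907 genes called between dark_42 and dark_14 became 284 without dark_14 a, 492 without dark_14 b and 489 without dark_42 b.

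**Figure D3:**
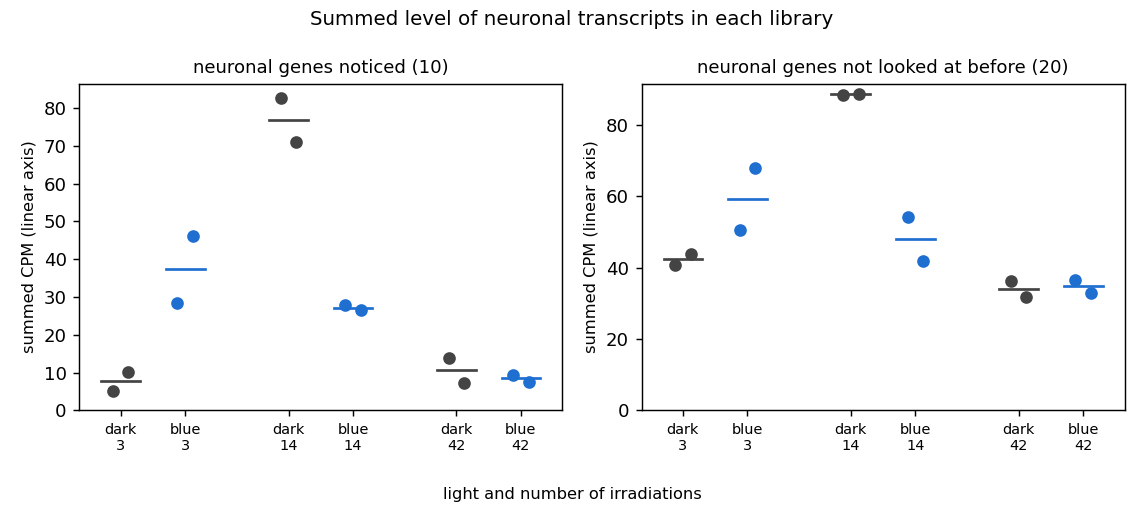
Summed CPM (linear axes) of the 10 neuronal transcripts first noticed (left) and of 20 others listed before they were looked at (right), in each library. Points are libraries and lines group means; the group means on the left are 7.68 CPM in dark_3, 37.3 in blue_3 and 76.8 in dark_14.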

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

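Among the tests below, those of a response of neuronal transcripts to light, of the series of library numbers, of the departure of the dark cultures at 42 irradiations, of the thinned sums of the neuronal genes first noticed and of those in dark_14 against dark_3, of the glial genes under 5 CPM and of the part UGT8 and PTPRZ1 held in the glial sum were chosen only after the result was seen.

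The effect of blue light differed between irradiation numbers for 5, 56 and 7 genes (14 against 3, 42 against 3, and 42 against 14 irradiations), by a test of the difference itself. Between 14 and 3 irradiations the log2 differences in effect were -3.44 for SYT1, -1.26 for MAP2, -0.99 for MRFAP1L1, -4.88 for CELF4 and -4.55 for NEFM. Between 42 and 3 irradiations they were 3.39 for SFRP1, 1.81 for OLFM4, 1.51 for CALB2, 1.51 for LRRC41, 1.39 for FLG and 1.21 for SAMD10. In the other direction they were -2.89 for B3GALT5, -1.62 for BMP3, -1.51 for CEACAM6, -1.503 for NEDD9 and -1.38 for ISG15. Between 42 and 14 irradiations they were 2.80 for SFRP1, 1.56 for OLFM4, 1.504 for CALD1, 1.15 for MED24, 0.95 for CDH2 and -1.01 for VAV3.

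Neuronal transcripts were higher in blue_3 than dark_3, and highest in dark_14. A response to blue light in 1 direction is argued against as the only cause, since dark_14 exceeded dark_3 with no light. The 20 neuronal genes listed before their sum was seen were also lower in blue_14 than in dark_14. Their log2 difference was -0.88 ± 0.16 (edgeR adjusted p = 0.246 over all genes). A source that raised dark_14 alone would give this sign whatever light does, so a response to light beside such a source stays open. For depth, the test as first written thinned all libraries to the smallest total. It gave 0.34 ± 0.19 for blue_3 against dark_3 on those 20 genes. Its bound of 1 could decide nothing, because the full libraries gave only 0.47. The 10 genes first noticed gave 2.51 ± 0.42 after thinning, but were picked for this difference. For dark_14 against dark_3 the 20 genes gave 1.04 ± 0.18 after thinning. Thinning keeps the expected share of each gene in a library, so these values decide nothing on depth. The unthinned sums, compared after the result was seen, argue against depth. The 20 genes summed to 40.8 and 43.8 CPM in dark_3 at totals of 6452030 and 7027034 counts. In blue_3 they summed to 50.4 and 67.8 CPM at totals of 7640273 and 6220751 counts. The smallest of these totals thus had the highest sum. In dark_14 a and b they summed to 88.5 and 88.7 CPM, at totals of 3561392 and 7950222 counts. RNA from neural tissue, a candidate source and a hypothesis, stays open: 17 glial genes differed by -0.01 ± 0.22 between blue_3 and dark_3 (-0.014), under the bound of 0.5 set beforehand, but UGT8 and PTPRZ1 held 92.3 of their 97.6 CPM in dark_3, which would hide a small share, and the other 15 gave 0.21 ± 0.32 in blue_3 and 1.42 ± 0.30 in dark_14 against dark_3. Of the 20 neuronal genes, 3 lay above 5 CPM in dark_3. NRGN stood at 8.79 CPM in dark_3 and 25.2 in dark_14, but CNTNAP2 at 14.2 and 9.64 and INA at 6 and 3.65. The myelin gene MOG had no count in any library and so says nothing about the source. Among the other glial genes, MAG stood at 0.14 CPM in dark_3 and 1.21 in dark_14, and CLDN11 at 0.15 and 1.3. MAL, at 2.73 and 2.35, and GJB6, at 0.59 and 0.2, went the other way. Haemoglobin genes summed to 1.39 CPM in dark_3 and 24.2 in dark_14 (5.05 and 43.4 in its libraries), and 10 liver, muscle, pancreas and kidney genes to 0.15 to 1.05 CPM in each group.

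Dark cultures differed between irradiation numbers, with 2284 genes called between dark_42 and dark_3. Library numbers form 2 series, 1 holding the 42-irradiation libraries, and this is argued against as the whole cause by the 1638 genes called between dark_14 and dark_3, which belong to 1 series. Neural RNA is argued against as the whole cause for dark_42 against dark_3, where 2045 genes were called with the neuronal sum as a covariate. For the comparisons with dark_14 that covariate left 28 and 0 calls, but it takes its highest values in dark_14 and so removes much of the group difference itself. Time in culture, which the design gives, stays open and was not tested apart from the library series at 42 irradiations.

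More genes were called after 42 irradiations than after 3 or 14. Depth is argued against, since with the 42-irradiation libraries thinned to the totals at 14 irradiations a median of 91.5 genes was called (75 to 118 over 10 draws). A single library cannot be told apart from the loss of a replicate, since 24 genes were called without blue_42 b, 32 without blue_42 a and 35 without dark_42 b, against 235 without dark_42 a. A departure of the dark_42 cultures is a candidate explanation, as a hypothesis: for 129 of the 158 genes, 81.6%, dark_42 lay farther from the mean of dark_3 and dark_14 than blue_42 did. An effect of blue light that offsets a change over time in culture would give the same values and stays open as well. The share over all tested genes was not computed, so the 81.6% cannot be called particular to the called genes.

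The average of the blue light effects called 9 genes. As many were called by 6 of 100 splits of the libraries within irradiation number, out of 108 possible, the real one included, so chance is not excluded. But the other splits that called 51, 27, 61 and 10 genes kept both blue_42 libraries together against both dark_42 libraries. They thus carried the real grouping at 42 irradiations, and the count of splits cannot decide on chance either way. The highest other split called 317 genes, several times the real count, which points to a structure of the samples. It set dark_3 a and b, dark_14 b, blue_14 a, dark_42 a and blue_42 a against the rest, and so parted the letters at 42 irradiations. Within each irradiation number, these libraries had the lower values on the first principal component. At 14 irradiations these values were 3.22 for dark_14 b and 6.61 for blue_14 a, against 16.1 for dark_14 a and 21.8 for blue_14 b. What this component reflects was not tested.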

How the results depend on the processing

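The fits with the neuronal sum as a covariate, without the 14-irradiation libraries and on thinned counts were chosen only after the result was seen. With RLE scaling all 131 values of named genes kept their direction and side of the threshold, as did 119 with DESeq2, 127 without robust estimation and 70 with the neuronal covariate. In order of the comparisons after 3, 14 and 42 irradiations, the differences 14 against 3, 42 against 3 and 42 against 14, and the average, the full fit called 2, 0, 158, 5, 56, 7 and 9 genes. Without a filter on low counts these were 54, 14, 420, 115, 288, 80 and 87, with 1, 2 and 3 genes shared between 3 and 14, 3 and 42, and 14 and 42. DESeq2 called 1 gene after 3 irradiations, 2 after 14, 15 and 25 for the differences 14 against 3 and 42 against 14, and 21 for the average. A filter at 5 CPM gave 0 after 3 irradiations and 3 for 14 against 3, and non-robust estimation 0 and 8. With only the libraries compared the calls were 22 after 3 irradiations, 100 after 42, 12 for 14 against 3, 2 for 42 against 14, 2651 for dark_14 against dark_3 and 443 for dark_42 against dark_14, with 1 gene shared between 3 and 42. With the neuronal covariate they were 1 after 3 irradiations, 1, 2 and 1 for the differences in the order above, 28 for dark_14 against dark_3 and 0 for dark_42 against dark_14, with 1 gene shared between 3 and 42. That covariate turned the log2 difference of dark_42 against dark_14 to 0.52 for FAM107A, 1.11 for SPARCL1, 1.96 for SNAP25 and 0.60 for MAP1B, with adjusted p of 0.666 to 0.925. Without the 14-irradiation libraries the calls were 8 after 3 and 246 after 42 irradiations, with 1 shared, and thinned counts gave medians of 0 and 91.5. At the preset correlation 10, 10 and 7 lists moved after 3, 14 and 42 irradiations, against 0, 0 and 0 with an estimated correlation and 0, 0 and 3 by fry. Leaving out 1 library gave 0 to 6 calls after 3 irradiations, 0 to 11 after 14 and 24 to 235 after 42. It gave 1 to 38, 2 to 209 and 2 to 53 for the differences, and 2 to 22 for the average. For the dark controls it gave 336 to 1987, 765 to 2574 and 284 to 1113 (14 against 3, 42 against 3, 42 against 14). Shared genes then numbered 0 to 0, 0 to 1 and 0 to 0, and lists 0 to 14, 4 to 17 and 3 to 9. An arm left with 1 library is assumed to vary like the other groups. The cause of these changes was not tested, except that fits on fewer libraries estimate the spread from fewer.

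Deviations of a from b correlated between blue and dark by 0.092, -0.287 and 0.405 at 3, 14 and 42 irradiations, and since these were not alike the replicate letters were not taken as pairs. At 42 irradiations the first principal component also parted the letters alike, at 2.71 for a and 16.1 for b in dark_42 and 3.32 and 13.8 in blue_42, so a factor shared by letter stays open there. With 1 letter term as a replicate block 0 genes were called after 3 irradiations, 169 after 42, 92 for 42 against 3 and 4 for the average. With a replicate block within irradiation number there were 11 after 3 irradiations, 160 after 42, 15 for 14 against 3, 5 for the average, and 697, 1017 and 368 between the dark controls in the order above, with 1 gene shared between 3 and 42. The cause was not tested.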

Other observations

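Markers of other cell types, listed before the data were examined, were low in these keratinocytes. Leukocyte markers, which include CD74, a chaperone of antigen presentation, summed to 2.56 and 2.94 CPM in the dark_3 libraries, 5.47 and 6.54 in blue_3, and 19.8 to 55.5 in the libraries at 14 and 42 irradiations. Fibroblast markers summed to 4.18 and 4.98 CPM in dark_3, 8.11 and 9 in blue_3, 14.6 and 14.97 in dark_14, 9.67 and 11.6 in blue_14, and 6.47 to 7.44 at 42 irradiations, melanocyte markers to 11.9 to 20.1 CPM and endothelial markers to 0.77 to 6.27 CPM over the 12 libraries. Opsins and other light-sensing proteins summed to 63.7 and 69.2 CPM in dark_3, 81.4 and 72.2 in blue_3, 48.3 and 50.3 in dark_42, and 55.7 and 53.9 in blue_42. At 14 irradiations blue and dark overlapped, at 74.4 and 71.1 CPM in dark_14 and 73.1 and 80.1 in blue_14.

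After 3 irradiations several single genes passed when adjusted over the list alone and not over all genes. On the terminal differentiation list these were FLG at -0.84 ± 0.16, IVL at 0.75 ± 0.15 and TGM1, which crosslinks the cornified envelope, at 1.02 ± 0.26, with adjusted p = 0.138, 0.138 and 0.338 over all genes by edgeR. Others were the stress-induced transcription factor ATF3 at 0.68 ± 0.16, the cell cycle inhibitor CDKN2B at 0.81 ± 0.17, the collagenase MMP13 at 0.93 ± 0.20 and the prostaglandin synthase PTGS2 at 0.93 ± 0.24. MYC differed by -0.79 ± 0.20 after 3 irradiations and by 0.61 ± 0.20 after 14, and passed only over its list in each.

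The first principal component held 45.9% of the variance and the second 19.9%.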
